A study of Mus musculus with 31 samples.

How the data were processed

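Kidneys of male mice on the B6 background were profiled by bulk mRNA sequencing. The mice were wild type (WT) or carried the Nbl1 genotype that the labels call HET, and they received cisplatin or phosphate-buffered saline (PBS) over 4 weeks from the age of 8 weeks. Kidneys were collected 3 days after treatment, at an age given as 11 weeks, which is less than the start and length of treatment add up to, and the sources used here do not settle this. The cisplatin dose and the kind of Nbl1 allele are not given in the sources used here. Per the labels' protocols, RNA was purified with a magnetic bead kit, samples with an RNA integrity number over 8 were kept, and libraries were made with the KAPA mRNA HyperPrep kit. The strand setting of the kit and of the counting is not given in the sources used here. Each of the 31 libraries carries its own animal number in its title, so each library was treated as 1 animal: 8 WT PBS, 8 WT cisplatin, 7 HET PBS and 8 HET cisplatin. All HET cisplatin animals are numbered between 600 and 629, while the other groups also hold animals outside that range, so the number range and the group are partly confounded.

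The deposited table holds 55487 genes with 3 values per library. Per the file headers and the values, these are counts, TPM and FPKM. The authors deposited expected counts that were estimated per gene and not normalized, as read from the values, of which 12.52%, in 26.38% of the genes, are not whole numbers. Per the submitters' processing notes, fastp, STAR and featureCounts and the builds GRCm38 and mm10 were used, and which tool gave the fractional counts is not given in the sources used here. Tool versions are not given in the sources used here. The deposited FPKM values equalled a constant multiple of the deposited TPM values within each library to 0.164% at a TPM over 5 and were not used further. The expected counts were rounded to whole numbers before testing. Every gene name comes from the deposited table, and 55227 of its gene identifiers were found in the GENCODE M21 annotation of GRCm38, from which coordinates were taken (19244 of the tested genes).

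Tests used edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group) in R 4.3.3, with limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and version 1.17.8 of the package data.table. The filter left 19268 genes. A single model with 4 group means and no covariate was fitted to all 31 libraries, so that all groups share 1 estimate of the spread, and 6 contrasts were taken from it: cisplatin against PBS in each genotype, HET against WT under each treatment and averaged over treatments, and the interaction, which is the difference between the cisplatin responses of HET and WT. P-values were adjusted by Benjamini-Hochberg over the tested genes within each contrast, with a threshold of 0.05. Fold changes are log2 values with their standard error (SE), with a prior count of 0.125. CPM (counts scaled to a total of 1e6) were computed from the expected counts with TMM scaling. A fold against a group at 0 counts was computed against a floor of 3 counts over the whole group. Intervals and floors cover counting error only.

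Gene lists (39, of which 36 had at least 3 tested members) were fixed beforehand and cover tubular injury, p53 targets, DNA repair, cell cycle, nephron segments, other kidney and immune cell types, metabolism, stress responses, BMP signalling, tissues that could adhere to a kidney, genes next to Nbl1 and genes that check sex. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, one way. Members are counted as past the threshold over all tested genes and, beside it, adjusted over the list alone. Per-library list scores are means of log2 CPM over the members, with a prior count of 2, compared by two-sided exact permutation tests, which were also used for Nbl1 and Htr6.

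Genes named in the text follow a rule: Nbl1; the 15 largest rises and 15 largest falls of each cisplatin contrast among genes past the threshold with a mean CPM of at least 1 in the higher group and a regular symbol; up to 4 members of each list with the smallest p; the 5 smallest p of each genotype contrast; and the genes next to Nbl1. The groups, tests, lists, naming rule and main alternatives were chosen before the data were examined. Those alternatives were DESeq2, limma voom with quality weights, RLE scaling, other low-count filters, fits of the compared groups alone, the number range 600 to 629 alone or as a covariate, the library number as a covariate, 2 surrogate variables, limma on log2(TPM + 1), and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out 5 libraries whose Nbl1 or Htr6 reads go against their label, leaving out 3 libraries that stand apart (WT cisplatin 6, HET cisplatin 6 and the library labelled HET cisplatin 4), leaving out HET cisplatin 6 in the list tests of the genotype contrasts and the interaction, an estimated correlation in those list tests with libraries left out, scaling by library totals alone, thinning all libraries to the smallest total, and clock phase as a covariate.

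Total counts ran from 24.65e6 to 37.3e6 per library. The median half-width of the 95% confidence interval of a log2 fold change was 0.256 for cisplatin in WT, 0.265 for cisplatin in HET, 0.264 for genotype under PBS, 0.253 for genotype under cisplatin, 0.183 for genotype averaged over treatments and 0.366 for the interaction. The fit was tested on simulated data, with counts drawn from the means and library sizes of the real samples and known fold changes set in a random choice of genes. Of genes changed 2-fold, it recovered 79.1% for cisplatin in WT (18843 genes tested), 76.1% for cisplatin in HET (18872), 77.6% for genotype under PBS (19076), 79.1% for genotype under cisplatin (19071), 88.1% for genotype averaged (19035) and 61.2% for the interaction (19056), and it called between 2 and 9 unchanged genes. At 1.5-fold the interaction recovered 41.8%. The simulated counts were drawn for each gene separately, without variation shared between genes. The genes set to change also outnumbered those called in the real genotype contrasts and interaction, which eases the adjusted threshold. For those contrasts the recovery may therefore be overstated and the calls of unchanged genes understated. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per gene between 2 libraries of a group was 9.955, over genes with at least 50 counts in the pair. Replicate numbers name the animals and pair no samples across groups.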

Results

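Kidney transcriptomes were obtained from 31 male mice, 1 library per mouse: 8 WT and 7 HET mice given PBS, and 8 WT and 8 HET mice given cisplatin. Cisplatin is a platinum drug that cross-links DNA and damages the kidney tubule, and PBS is the buffer given to the controls. Nbl1 is the gene altered in the HET mice. Total counts, in units of 1e6 per library, were 29.85 to 37.3 in WT PBS, 29.23 to 36.7 in HET PBS, 24.65 to 28.86 in WT cisplatin and 26.87 to 31.92 in HET cisplatin. The first principal component held 73.5% of the variance of the 2000 most variable genes and separated the PBS libraries (−62.63 to −51.81) from the cisplatin libraries (15.85 to 78.87), and the second held 3.1%. Mitochondrial transcripts made up 8.41% ± 0.28 (SD, n = 8) of the counts in WT PBS and 3.44% ± 0.77 (SD, n = 8) in WT cisplatin, with 8.36% ± 0.19 (SD, n = 7) and 3.87% ± 0.66 (SD, n = 8) in the HET groups. The share of Malat1, a nuclear long noncoding RNA, went the other way, from 1.64% ± 0.14 (SD, n = 8) to 3.31% ± 0.6 (SD, n = 8) in WT and from 1.67% ± 0.13 (SD, n = 7) to 3.07% ± 0.57 (SD, n = 8) in HET, so the make-up of the libraries differs between treatments in both.

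The first question was whether the targeted gene reads as the labels say. Nbl1 (ENSMUSG00000041120, chromosome 4, bases 139082284 to 139092993 of GRCm38, minus strand) encodes a secreted antagonist of bone morphogenetic proteins (BMPs). Under PBS its level was 2.72 ± 1.7 CPM (SD, n = 7) in HET and 6.37 ± 1.3 CPM (SD, n = 8) in WT. The HET mean stood at 42.8% of WT, and mean log2 CPM differed by −1.8 (exact permutation test of log2 CPM, p = 0.000466). Under cisplatin it was 7.34 ± 4.7 CPM (SD, n = 8) in HET and 20.6 ± 4.8 CPM (SD, n = 8) in WT. The HET mean stood at 35.5% of WT, and mean log2 CPM differed by −1.94 (exact permutation test of log2 CPM, p = 0.000466). Both shares average over HET libraries that differed widely, as given below. Cisplatin raised Nbl1 in both genotypes, by a log2 fold change of 1.70 (SE 0.42, adjusted p = 0.000784) in WT and 1.43 (SE 0.46, adjusted p = 0.00839) in HET, and the interaction was −0.27 (SE 0.61, adjusted p = 0.974).

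The HET groups were not uniform at Nbl1. The libraries labelled HET PBS 1 and 6 held 0.106 and 0.434 CPM, from 3 and 13 counts, against 3.26 to 4.2 CPM in the other 5 HET PBS libraries. The libraries labelled HET cisplatin 3 and 4 held 1.08 and 0.859 CPM, from 37 and 31 counts, against 4.67 to 13.9 CPM in the other 6. As a share of the WT mean under the same treatment, these 4 libraries stood at 1.67% (95% counting interval 0.345 to 4.89), 6.82% (3.63 to 11.7), 5.22% (3.68 to 7.2) and 4.17% (2.83 to 5.91). The library labelled WT PBS 6 held 3.71 CPM, against 5.82 to 7.9 CPM in the other 7 WT PBS libraries. WT cisplatin 6 was also low, at 10.7 CPM against 18.1 to 26.2 CPM in the rest of its group. It held 0 counts of Htr6, described below, and was not counted among the libraries that go against their label. The 5 libraries named before it go against their genotype label at this locus. Every genotype difference given here keeps the labels as they are, with the values without these 5 libraries where they change a gene or list call. The 5 were picked by their Nbl1 and Htr6 values. Calls of Nbl1, of Htr6 or of the genes around Nbl1, which include Htr6, are therefore no separate evidence when the 5 are left out.

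**Figure D1:**
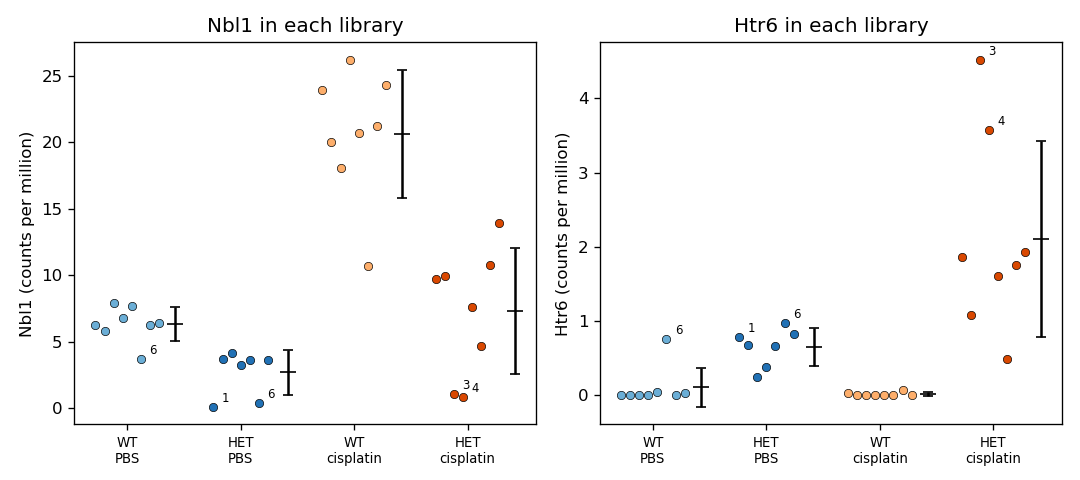
CPM of Nbl1 (left) and Htr6 (right), 1 point per library in the 4 groups, with bars for the mean and SD; numbers mark the 5 libraries that go against their genotype label. Nbl1 is lower in HET, near 0 in 4 libraries labelled HET, and Htr6 is found in every HET library and, among the WT libraries, mostly in 1 labelled WT PBS, at 0.756 CPM against at most 0.0677 CPM in the others.

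Htr6, the gene of a serotonin receptor, lies 6713 bases downstream of Nbl1 on the same strand (ENSMUSG00000028747, chromosome 4, bases 139061108 to 139075570 of GRCm38) and was present in HET kidneys. Under cisplatin the HET libraries held 569 counts in all and the WT libraries 3, a ratio of 175 (95% counting interval 59.6 to 852; exact permutation test, p = 0.000155, n = 8 per group). Under PBS the counts were 131 in HET and 24 in WT, a ratio of 6.35 (4.09 to 10.3; exact permutation test, p = 0.0042, n = 7 and 8), and 22 of the 24 came from the library labelled WT PBS 6. The libraries labelled HET cisplatin 3 and 4, which had little Nbl1, held the most Htr6 of their group, 4.52 and 3.58 CPM against 0.48 to 1.93 CPM in the other 6. Of the 16 tested genes around Nbl1, Htr6 rose in HET under cisplatin and the other 15 did not pass the threshold (1 gene adjusted over the list alone). The list passed camera under cisplatin (adjusted p = 0.00258) and averaged over treatments (0.0105) but not with an estimated correlation (adjusted p = 0.56 and adjusted p = 0.78). Of the genes that check sex, 4 on the Y chromosome were tested, and none of them differed by genotype under either treatment.

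Cisplatin against PBS asks what the drug did to the kidney in each genotype. Markers of tubular injury rose in both: all 22 tested markers were higher in WT and all 22 in HET, with the same counts adjusted over the list alone and medians of 2.80 and 2.57 log2 units. Havcr1, which encodes kidney injury molecule 1, rose from 1.62 ± 0.46 to 253 ± 81 CPM in WT (SD, n = 8 each; log2 fold change 7.29, SE 0.42, adjusted p = 1.6e-15) and from 2.49 ± 1.5 (SD, n = 7) to 278 ± 140 CPM (SD, n = 8) in HET (6.80, SE 0.43, adjusted p = 2.06e-14). Lcn2, the neutrophil gelatinase-associated lipocalin of injured tubules, rose by 7.48 (SE 0.35, adjusted p = 1.17e-17) in WT and 6.05 (SE 0.34, adjusted p = 1.62e-15) in HET. Krt20, a keratin, rose by 7.22 (SE 0.47) and 6.65 (SE 0.47), and the secreted phosphoprotein gene Spp1 reached 4970 ± 470 CPM in WT and 4270 ± 900 CPM in HET (SD, n = 8 each) from 428 ± 50 (n = 8) and 496 ± 40 (n = 7). The list passed camera in WT (adjusted p = 1.41e-22) and HET (5.02e-19), and with an estimated correlation (0.015 and 0.043).

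Target genes of p53, the transcription factor of the DNA damage response, rose next to the injury markers. In WT 26 of 30 rose, 1 fell and 3 did not pass (27 and 1 adjusted over the list alone), and in HET 25 rose, 1 fell and 4 did not pass (25 and 1 adjusted over the list alone). Eda2r, a death receptor, rose by 7.64 (SE 0.19, adjusted p = 8.83e-25) in WT and 6.89 (SE 0.19, adjusted p = 1.76e-23) in HET. Psrc1 rose by 6.83 (SE 0.22) and 6.79 (SE 0.23), Zfp365 by 7.84 (SE 0.34) and 7.57 (SE 0.35), and the more abundant Ccng1, a cyclin G, by 2.32 (SE 0.063) and 2.45 (SE 0.066). Camera gave an adjusted p of 7.33e-39 in WT and 1.95e-41 in HET, and 0.0017 and 0.0012 with an estimated correlation. Of 25 DNA repair genes, 12 rose in each genotype, 2 fell in WT and 1 in HET (18 and 21 rose and 1 fell in each with library totals), with the same counts adjusted over the list alone and camera at 0.159 and 0.134. Rev1, a translesion polymerase, rose by 0.94 (SE 0.065) and 1.01 (SE 0.068), and Rad51c, a recombination factor, fell by 1.27 (SE 0.16) and by 1.48 (SE 0.16). Among cell cycle genes 6 of 25 rose and 1 fell in WT (5 and 1 adjusted over the list alone), 5 rose and 1 fell in HET (5 and 1), and camera gave 0.601 and 0.578, while with library totals 14 rose in WT and 12 in HET and 0 fell. Rrm2, a ribonucleotide reductase subunit, rose by 1.28 (SE 0.18) and 1.02 (SE 0.19).

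Genes of the proximal tubule, the segment that takes up cisplatin, fell. Of 18 genes of its first and second segments (S1 and S2), 17 fell in WT and 17 in HET, with medians of −1.74 and −1.62 and the same counts adjusted over the list alone. Lrp2, the endocytic receptor megalin, went from 7210 ± 440 to 1300 ± 700 CPM in WT (SD, n = 8 each) and from 6730 ± 530 (SD, n = 7) to 1590 ± 680 CPM (SD, n = 8) in HET. The organic anion transporter gene Slc22a6 fell by 2.93 (SE 0.35) and by 2.61 (SE 0.35), and the phosphate transporter gene Slc34a3 by 4.72 (SE 0.42) and by 3.88 (SE 0.40). Of 12 genes of the last segment (S3), 10 fell in each genotype (10 adjusted over the list alone) with medians of −2.46 and −2.36, and with library totals 2 rose in WT and 1 in HET. Slc22a7, an organic anion transporter, fell by 6.24 (SE 0.21, adjusted p = 2.62e-21) in WT and by 6.15 (SE 0.21, adjusted p = 4.75e-21) in HET, and the amino acid transporter gene Slc7a13 fell by 7.46 (SE 0.62) and by 7.40 (SE 0.62). Camera called both lists in WT (1.79e-06 for S1 and S2, 2.29e-10 for S3) and HET (2.12e-05 and 1.18e-11). The calls were lost with an estimated correlation, at adjusted p = 0.52 and adjusted p = 0.63 for S1 and S2, and adjusted p = 0.076 and adjusted p = 0.086 for S3.

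Genes that androgens maintain in the male mouse kidney all fell, 10 of 10 in each genotype (10 adjusted over the list alone), with medians of −4.46 in WT and −4.28 in HET. Kap, the kidney androgen-regulated protein, went from 15500 ± 420 to 344 ± 88 CPM in WT (SD, n = 8 each) and from 15500 ± 860 (SD, n = 7) to 263 ± 95 CPM (SD, n = 8) in HET. Slco1a1, an organic anion transporter, changed by −7.81 (SE 0.57) and −7.98 (SE 0.57), and Slc22a28 by −7.37 (SE 0.68) and −7.37 (SE 0.68). Camera gave 1.11e-11 in WT, where the call held with an estimated correlation (0.026), and 1.14e-12 in HET, where it did not (adjusted p = 0.052). Cisplatin handling genes went both ways, though the ones named below all fell. Of 16, 7 rose and 6 fell in WT and 9 rose and 6 fell in HET (the same counts adjusted over the list alone), with medians of 0.29 and 0.32, means of −0.10 and −0.10, and camera at 0.795 and 0.84. With library totals 10 rose and 5 fell in WT and 10 rose and 4 fell in HET. Slc22a2, the cation transporter that carries cisplatin into the tubule, fell by 3.02 (SE 0.27) and by 2.74 (SE 0.27), Slc47a1, an exporter, changed by −1.96 (SE 0.15) and −1.69 (SE 0.15), the copper transporter gene Slc31a1 by −1.15 (SE 0.080) and −1.08 (SE 0.082), and Ggt1, a glutathione-cleaving enzyme, by −2.75 (SE 0.24) and −2.47 (SE 0.24).

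Mitochondrial metabolism followed the tubule genes. All 16 oxidative phosphorylation genes fell in both genotypes (16 adjusted over the list alone, medians −1.03 and −0.92). Of 17 fatty acid oxidation genes, 14 fell and 1 rose in each genotype (2 rose in WT adjusted over the list alone), and Acadl, an acyl-CoA dehydrogenase, fell by 1.20 (SE 0.075) and by 1.20 (SE 0.077). Camera called both lists, at 1.28e-12 and 2.18e-12 for oxidative phosphorylation and 1.04e-05 and 5.18e-07 for fatty acid oxidation. With an estimated correlation these calls were lost (adjusted p = 0.27 and adjusted p = 0.28, then adjusted p = 0.52 and adjusted p = 0.48). In cholesterol synthesis 8 of 13 genes fell and 3 rose in WT, and 6 fell and 4 rose in HET (the same counts adjusted over the list alone). The list's median of −0.25 in HET turned to 0.15 when libraries were scaled by their totals, with 5 lower and 5 higher. Hmgcs1, an enzyme of the pathway, fell by 1.76 (SE 0.14) and by 1.70 (SE 0.15). Camera called that list in WT (0.0183), not with an estimated correlation (adjusted p = 0.66), and not in HET (0.134). NRF2 targets, genes of the oxidative stress response, rose: 9 of 14 in WT and 10 of 14 in HET, with 1 lower in each (10 and 1, and 10 and 2, adjusted over the list alone). Nqo1, a quinone reductase, rose by 1.76 (SE 0.14) and 1.80 (SE 0.15), and Gsta1, a glutathione transferase whose reads may be shared with a near-identical copy, by 8.67 (SE 0.31) and 8.18 (SE 0.31). Camera gave 0.00131 and 0.00125 for that list, and adjusted p = 0.52 and adjusted p = 0.48 with an estimated correlation.

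Matrix and macrophage genes were higher. Of 16 extracellular matrix and fibrosis genes, 15 rose in WT and 13 in HET (16, and 14 with 1 lower, adjusted over the list alone), and camera gave 0.00272 and 0.0131, with adjusted p = 0.62 and adjusted p = 0.63 with an estimated correlation. Timp1, an inhibitor of matrix proteases, rose by 4.26 (SE 0.38) and 3.47 (SE 0.38), and the collagen gene Col4a1 by 0.64 (SE 0.094) and 0.64 (SE 0.098). Of 11 macrophage genes, 10 rose and 1 fell in WT and 9 rose and 1 fell in HET (the same counts adjusted over the list alone). Itgam, an integrin of myeloid cells, rose by 3.40 (SE 0.37) and 2.20 (SE 0.36), while Csf1r, the receptor for macrophage colony-stimulating factor, fell by 0.71 (SE 0.098) and by 0.84 (SE 0.10). Camera called the macrophage list in WT (0.0183), not with an estimated correlation (adjusted p = 0.66), and not in HET (0.152). Among 13 inflammatory cytokine and NF-kB genes, 9 rose and 1 fell in WT and 8 rose in HET (9 and 1, and 9, adjusted over the list alone), with camera at 0.0548 and 0.0593. Cxcl2, a neutrophil-attracting chemokine, rose by 4.36 (SE 0.58) and 3.72 (SE 0.60). All 10 endothelial genes fell in both genotypes (10 adjusted over the list alone), though their medians of −0.44 and −0.37 became −0.05 and 0.03 when libraries were scaled by totals, with 5 lower and 2 higher in WT and 2 lower and 3 higher in HET. Emcn, endomucin, fell by 0.91 (SE 0.053) and by 0.70 (SE 0.054), against the typical gene. Camera gave 0.000578 and 0.003 for them, and adjusted p = 0.076 and adjusted p = 0.16 with an estimated correlation. Erythrocyte genes fell, 6 of 6 in WT and 5 of 6 in HET (6 and 5 adjusted over the list alone; 5 fell and 1 rose in each with library totals), with medians of −7.58 and −7.08, camera at 0.0301 and 0.0307 and adjusted p = 0.59 and adjusted p = 0.63 with an estimated correlation. Alas2, the erythroid heme synthesis enzyme, fell by 6.99 (SE 0.52) and by 6.58 (SE 0.53). The globin genes Hba-a1 (−7.76, SE 0.83, and −7.21, SE 0.82) and Hbb-bs (−7.70, SE 1.0, and −7.67, SE 1.0) have near-identical copies, so their single values are uncertain.

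Farther along the nephron the changes were mixed. Of 10 thick ascending limb genes 7 fell and 3 rose in each genotype (the same adjusted over the list alone; camera 0.159 and 0.238; 5 and 4 fell and 3 rose with library totals), with Egf, the epidermal growth factor, falling by 4.07 (SE 0.35) and by 3.62 (SE 0.35). In the distal convoluted tubule 7 of 8 genes fell in each, and 1 rose in WT (the same adjusted over the list alone; 4 and 5 fell and 1 rose in each with library totals). Pvalb, a calcium-binding protein, fell by 6.80 (SE 0.54) and by 6.27 (SE 0.52), and Slc12a3, the thiazide-sensitive cotransporter, by 1.66 (SE 0.15) and by 1.42 (SE 0.15). Camera called that list at 0.0222 and 0.00436, and not with an estimated correlation (adjusted p = 0.52 and adjusted p = 0.28). Collecting duct principal cell genes rose in 7 of 9 cases in WT and 5 of 9 in HET (7 and 6 adjusted over the list alone; 9 in each with library totals; camera 0.101 and 0.179), with Aqp2, a water channel, up by 0.74 (SE 0.13) and 0.70 (SE 0.14).

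The largest changes lay outside the lists in part. Sprr2f and Sprr2g, of the family of small proline-rich proteins of cornified epithelium, rose, and the annotation lists Sprr2g as a polymorphic pseudogene. Sprr2f went from 0.0179 ± 0.038 to 21.7 ± 22 CPM in WT (SD, n = 8 each) and from 0.0237 ± 0.031 (SD, n = 7) to 19.1 ± 27 CPM (SD, n = 8) in HET, and Sprr2g rose by 7.14 (SE 0.63) and 6.99 (SE 0.66), with values that are uncertain because the Sprr2 genes are near-identical. Casp14, a caspase of the epidermis, held 1207 counts in WT cisplatin against 1 in WT PBS, a ratio of 1150 (95% counting interval 207 to 45600). In HET it was 288-fold higher against a floor of 3 counts over the group (lower end of the 95% counting interval 234). Cxcl17, a mucosal chemokine, was 188-fold higher in WT against the same floor (lower end of the interval 152) and 24.6-fold higher in HET (14.5 to 45.4), from 589 and 454 counts under cisplatin. Among the falls, Pzp, a protease inhibitor related to alpha-2-macroglobulin, went from 195 ± 25 to 0.228 ± 0.32 CPM in WT (SD, n = 8 each) and from 196 ± 28 (SD, n = 7) to 0.308 ± 0.29 CPM (SD, n = 8) in HET. Pde6a, a phosphodiesterase, fell by 9.06 (SE 0.37) and by 7.44 (SE 0.33), and Inmt, an N-methyltransferase, by 6.93 (SE 0.40) and by 6.33 (SE 0.39).

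With edgeR, 12174 of 19268 genes passed the threshold in WT, 6469 higher and 5705 lower (2014 and 1744 by at least 2-fold), and 11374 passed in HET, 5981 higher and 5393 lower (1820 and 1469 by at least 2-fold). Of the called genes 53.1% were higher in WT and 52.6% in HET. Scaling by library totals moved the median log2 fold change of all genes from 0.06 to 0.46 in both genotypes and the share called higher to 80.5% and 83.3%, so small changes are relative to the typical gene.

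**Figure D2:**
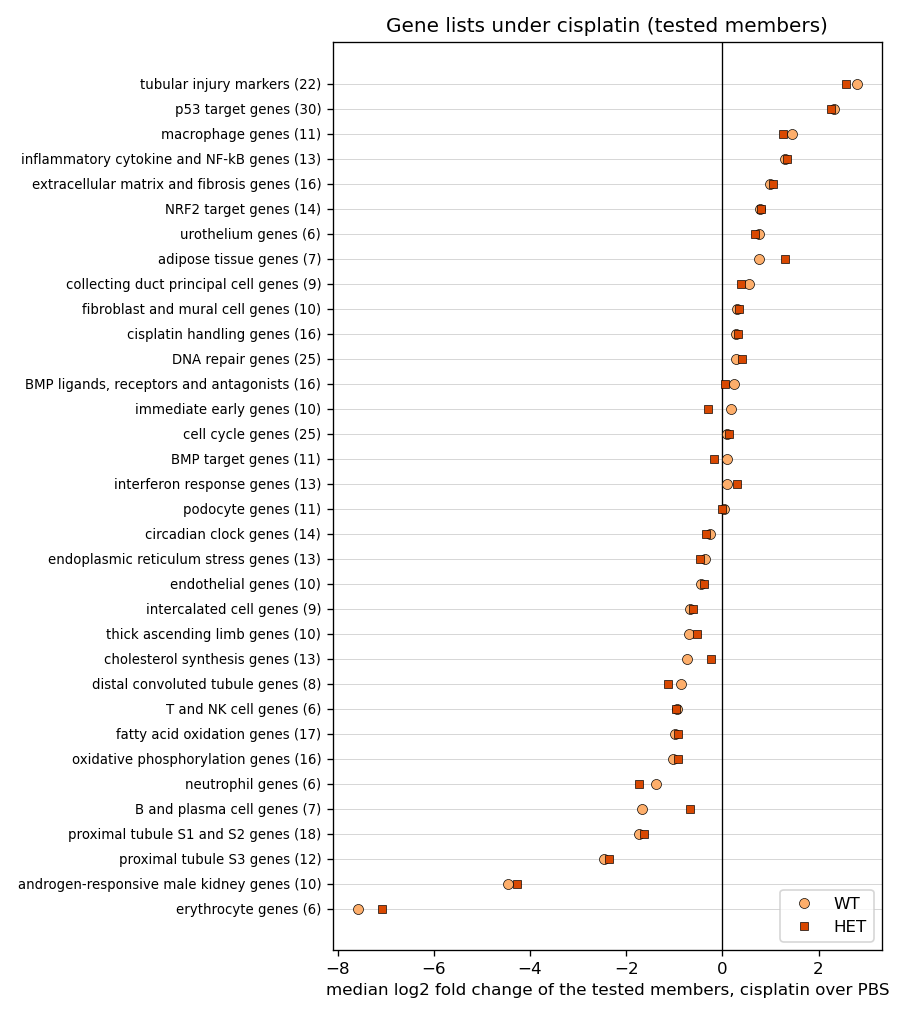
Median log2 fold change, cisplatin over PBS, of the tested members of each gene list in WT (circles) and HET (squares), with the number of tested members in brackets. Tubular injury markers (2.80 and 2.57) and p53 targets (2.33 and 2.26) stand high, and androgen-responsive genes (−4.46 and −4.28) and erythrocyte genes (−7.58 and −7.08) low, in both genotypes.

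The WT and HET responses were then set side by side. Slc22a7, an organic anion transporter gene, responded alike in both (interaction 0.10, SE 0.25), while for Lcn2 the interaction of −1.43 (SE 0.42) did not pass (adjusted p = 0.725). Across the 19268 genes the log2 fold changes of the 2 genotypes correlated with r = 0.947 and a slope of HET on WT of 0.879 (orthogonal slope 0.925). Genes are not independent replicates, and the 2 contrasts share no library. Of the called genes 10157 were called in both genotypes, 10152 of them in the same direction, which is 83.4% of the WT calls and 89.3% of the HET calls. Independent lists of these sizes would share 2008 higher and 1597 lower genes, against 5248 and 4904 observed. A further 2017 genes were called in WT alone and 1217 in HET alone, but the interaction had an unadjusted p under 0.05 for 296 and 201 of them, so most of these are not shown to differ between genotypes.

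**Figure D3:**
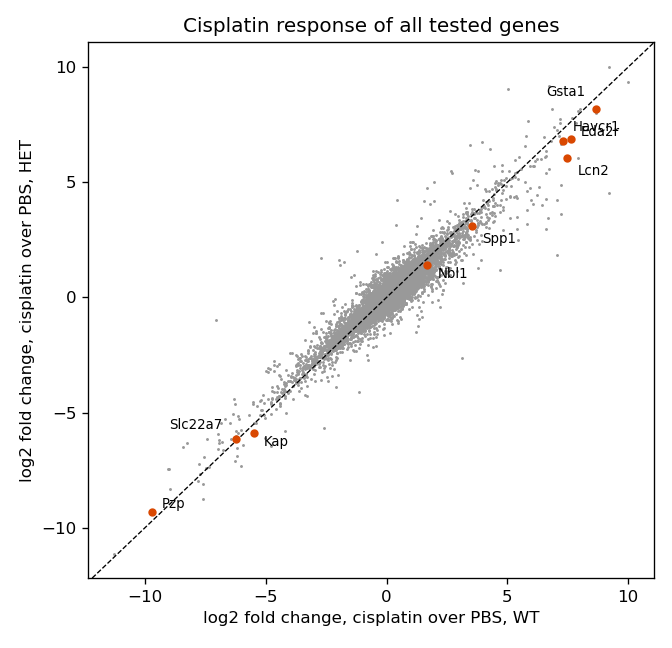
Log2 fold change of each of 19268 tested genes, cisplatin over PBS, in WT (x axis) and HET (y axis), with the line of equal change dashed and some named genes marked. The 2 sets of values correlate (r = 0.947). Among the marked genes they run from Pzp (−9.72 and −9.30) to Gsta1 (8.67 and 8.18), and some unmarked genes lie beyond these.

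HET against WT under PBS asks whether the Nbl1 genotype alone changed the kidney. The genes with the smallest p were Sesn2, a stress-induced metabolic regulator (log2 fold change 0.91, SE 0.17, adjusted p = 0.109), Trim46 (−0.94, SE 0.19), Rin2 (0.24, SE 0.049) and the muscarinic receptor gene Chrm3 (−0.68, SE 0.14), each at an adjusted p of 0.181, and Ypel2 (0.84, SE 0.18, adjusted p = 0.299). Sesn2 stood at 93.9 ± 42 CPM in HET (SD, n = 7) and 49.9 ± 9.3 CPM in WT (SD, n = 8). Like Nbl1, Sesn2 lies on chromosome 4 (bases 132492032 to 132510501 of GRCm38). Whether its level is tied to the Nbl1 locus was not tested. The 22 tubular injury markers had a median of 0.23, none passed the threshold singly, and their score was 4.14 ± 0.22 in HET (SD, n = 7) and 3.81 ± 0.25 in WT (SD, n = 8; exact permutation test, p = 0.0179, adjusted over 6 scores p = 0.107). Camera called that list alone (adjusted p = 5.04e-08), and the call was lost with an estimated correlation (adjusted p = 0.70). Adjusted over the list alone, 4 p53 targets, 3 genes of BMP ligands, receptors and antagonists, 2 clock genes and 1 gene around Nbl1 were higher. Without the 5 libraries that go against their label camera called 7 lists: injury (1.37e-07), p53 target (0.0197), fatty acid oxidation (0.0385), neutrophil (0.0385) and BMP target genes (0.0408) and the genes around Nbl1 (0.0385) higher, and interferon response genes (0.0385) lower. None of the 7 held with an estimated correlation (smallest adjusted p of any list 0.924). In edgeR 0 genes passed, with 968 at an unadjusted p under 0.05 (5.02%). DESeq2 called 5, the same 5 named first here, and limma voom and limma on TPM called 0. Htr6 passed without the library labelled WT PBS 6 (1 gene). Sesn2 passed without HET PBS 5 or without the library labelled HET PBS 6 (1 gene each). Sesn2 and 1 more gene passed without WT PBS 8 (2 genes), and Ypel2 without WT PBS 7 (1 gene). Without the 5 libraries that go against their label Htr6 and Sesn2 passed (2 genes). Those 5, WT PBS 6 among them, were picked by Nbl1 and Htr6, so these Htr6 calls are no separate evidence.

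HET against WT under cisplatin asks whether the genotype changed the injured kidney. Htr6 was the gene that passed in edgeR (log2 fold change 7.02, SE 0.84, adjusted p = 3.59e-05), and 1066 genes (5.53%) had an unadjusted p under 0.05. Next by p were Kng1, which encodes kininogen (−0.51, SE 0.11), and Serpinb1a, a protease inhibitor (−0.39, SE 0.090), each at an adjusted p of 0.551. Akr1b7 (3.26, SE 0.75) and Star (3.90, SE 0.90), genes of steroid-producing adrenal cells, had the same adjusted p of 0.551, and both values come from the library labelled HET cisplatin 4. There Star stood at 205 CPM against 1.28 to 2.11 in the rest of the group, and its log2 fold change without that library was −0.15. Nbl1 itself was at −1.49 (SE 0.42, adjusted p = 0.874). limma voom called Htr6 and Nbl1, and without the 5 libraries that go against their label edgeR called the same 2 genes. Those 5 were picked by these 2 genes, so the Nbl1 call gained without them is no separate evidence.

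Injury and tubule scores did not separate the genotypes under cisplatin. The injury score was 6.88 ± 0.46 in HET and 7.06 ± 0.20 in WT (SD, n = 8 each), a difference of −0.176 (exact permutation test, p = 0.391, adjusted over 6 scores p = 0.721). The p53 target score differed by 0.00354 (exact p = 0.972), the S1 and S2 score by 0.389 (exact p = 0.347), the S3 score by 0.187 (exact p = 0.436), the matrix score by −0.235 (exact p = 0.5) and the cell cycle score by −0.116 (exact p = 0.601). With each cisplatin library left out in turn the difference ran from 0.175 (without WT cisplatin 4) to 0.618 (without HET cisplatin 8) for S1 and S2, from 0.0765 (without WT cisplatin 4) to 0.31 (without WT cisplatin 6) for S3, from −0.344 (without HET cisplatin 2) to −0.000317 (without HET cisplatin 6) for matrix, from −0.195 (without WT cisplatin 3) to 0.0257 (without HET cisplatin 6) for cell cycle and from −0.09 (without WT cisplatin 6) to 0.0792 (without HET cisplatin 6) for p53 targets, and the injury difference from −0.238 (without HET cisplatin 8) to −0.0308 (without HET cisplatin 6). Camera called 11 lists here, and 0 with an estimated correlation or with fry. Of these, S1 and S2 (adjusted p = 4.43e-05), interferon response (0.000115), oxidative phosphorylation (0.000407), cholesterol synthesis (0.00101), fibroblast and mural cell (0.0386) and adipose genes (0.0448) were on the higher side in HET, and macrophage (0.000115), injury (0.00204), BMP target (0.0026) and matrix genes (0.0348) on the lower side. With an estimated correlation their adjusted p = 0.56 to adjusted p = 0.66, and no member passed the threshold singly. Adjusted over the list alone, 1 BMP target was lower and no other member of these 10 lists passed. Without HET cisplatin 6 the calls of matrix (adjusted p = 0.617), injury (0.5), macrophage (0.102) and oxidative phosphorylation genes (0.102) were lost, matrix genes lay on the higher side, and p53 targets were called higher (0.01). Without WT cisplatin 6, HET cisplatin 6 and the library labelled HET cisplatin 4, which stand apart, injury (0.0848), matrix (0.45) and adipose genes (0.278) were not called, and S3 (0.0228), androgen-responsive (0.0355) and cisplatin handling genes (0.0437) were called higher. Without the 5 libraries that go against their label, adipose (0.401), fibroblast and mural cell (0.171) and cholesterol synthesis genes (0.0852) were not called, and cell cycle genes (0.00154) were called lower and cisplatin handling genes (0.0266) higher. With an estimated correlation 0 lists were called in each of these 3 fits (smallest adjusted p 0.24, 0.218 and 0.227), so the gained calls did not hold either.

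**Figure D4:**
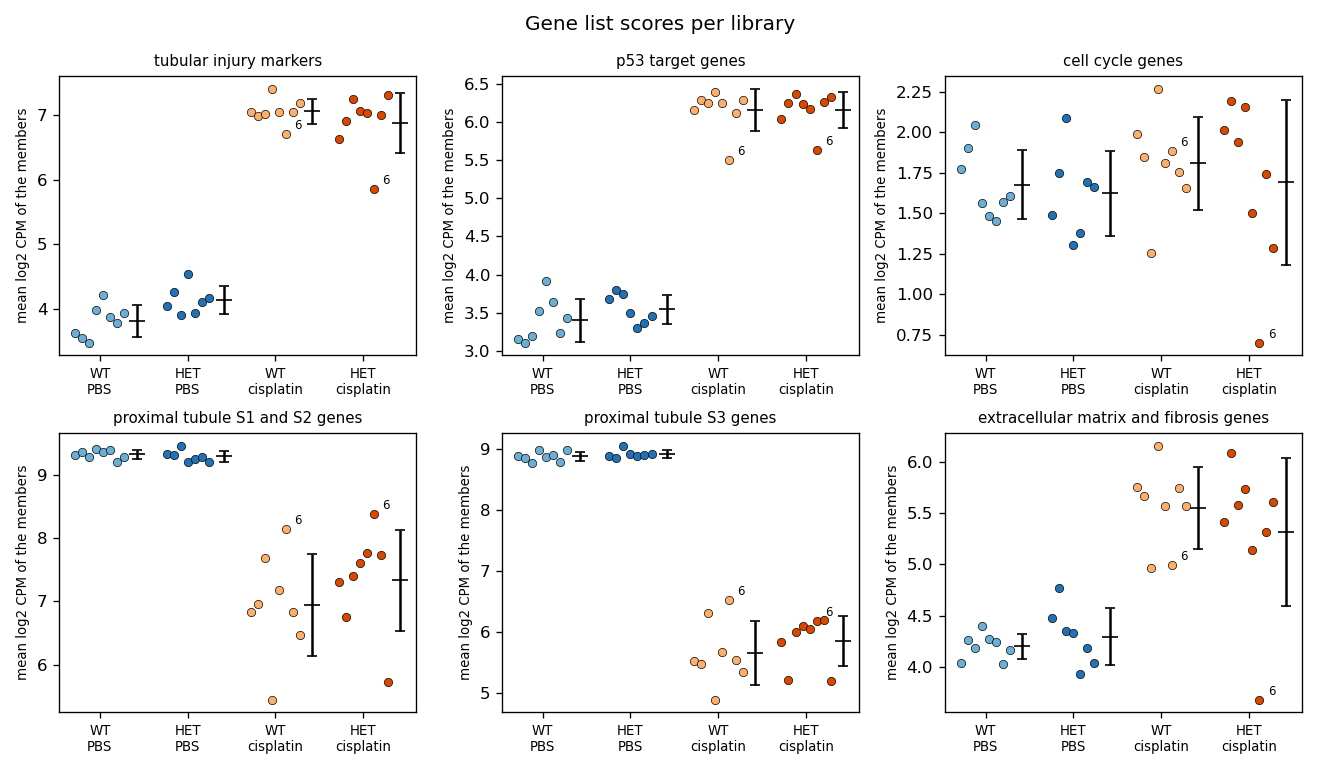
Score of 6 gene lists per library, the mean log2 CPM of the members, in the 4 groups, with bars for the mean and SD. WT and HET overlap under cisplatin in every list, and libraries WT cisplatin 6 and HET cisplatin 6 are marked, with injury scores of 6.71 and 5.87.

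Averaged over both treatments, Htr6 was again the gene that passed (4.82, SE 0.55, adjusted p = 1.27e-05), with 901 genes (4.68%) at an unadjusted p under 0.05. Kcnh1, a potassium channel gene, was lower in HET at an adjusted p of 0.313 (−0.95, SE 0.19), Sesn2 followed (0.53, SE 0.12, adjusted p = 0.458), Nbl1 was the fourth (−1.36, SE 0.31, adjusted p = 0.61) and Rgp1 the fifth (−0.13, SE 0.033, adjusted p = 0.983). DESeq2 called Htr6 and Kcnh1, while limma voom, limma on TPM and edgeR without the 5 libraries that go against their label called Htr6 and Nbl1. As those 5 were picked by Nbl1 and Htr6, the Nbl1 call without them is no separate evidence. Without the library labelled HET PBS 6, Htr6 and Sesn2 passed. Camera called 10 lists, of which DNA repair was lower (0.0105) and NRF2 targets (0.0105), oxidative phosphorylation (0.0105), S1 and S2 (0.0128), cisplatin handling (0.0232), fatty acid oxidation (0.0232), fibroblast and mural cell (0.0232), p53 target (0.0257) and endoplasmic reticulum stress genes (0.0361) were higher, besides the genes around Nbl1. None held with an estimated correlation (adjusted p = 0.78 to adjusted p = 0.91), and of their members Htr6 and 1 p53 target, Sesn2, passed adjusted over the list alone. In the shared range of animal numbers the p53 target and endoplasmic reticulum stress lists lay on the lower side (adjusted p = 0.957 and adjusted p = 0.53). Without HET cisplatin 6, S1 and S2 (0.295), fatty acid oxidation (0.457), oxidative phosphorylation (0.132), endoplasmic reticulum stress (0.155) and cisplatin handling genes (0.0657) were not called, and injury (0.00069) and adipose genes (0.0427) were called higher and erythrocyte genes (0.0282) lower. Without the 3 libraries that stand apart, p53 target (0.0592), fatty acid oxidation (0.304) and endoplasmic reticulum stress genes (0.481) were not called, and cholesterol synthesis (0.00199), injury (0.0148) and S3 genes (0.0167) were called higher. Without the 5 libraries that go against their label, endoplasmic reticulum stress (0.705) and fibroblast and mural cell genes (0.313) were not called, and cell cycle (0.00919) and macrophage genes (0.00956) were called lower. With an estimated correlation 0 lists were called in each of these 3 fits (smallest adjusted p 0.303, 0.904 and 0.0635).

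The interaction asks whether the response to cisplatin itself differed by genotype. Cxcl17 had the smallest p, with a response of at least 188-fold in WT and 24.6-fold in HET. WT PBS held 0 counts of it, so the size of its interaction has no upper bound and the fitted value, which depends on the prior count, is not given. Tacc2, a centrosomal protein gene (−0.44, SE 0.10), Dchs1, a protocadherin gene (0.49, SE 0.12), Trim30b (−1.67, SE 0.41) and Chrm3 (0.78, SE 0.20) followed, all 5 at an adjusted p of 0.725. edgeR called 0 genes, with 1079 (5.6%) at an unadjusted p under 0.05, and DESeq2, limma voom and limma on TPM also called 0. Camera called 10 lists, among them injury markers (median −0.43, adjusted p = 6.09e-10) and interferon response genes (median 0.39, adjusted p = 7.31e-05). None of the 10 held with an estimated correlation (adjusted p = 0.21 to adjusted p = 0.90) or with fry. Adjusted over the list alone, 2 matrix genes, 1 injury marker and 1 gene of BMP ligands, receptors and antagonists lay on the lower side in HET. Without HET cisplatin 6 the calls of matrix (0.692) and endothelial genes (0.0843) were lost and fatty acid oxidation genes were called lower (0.0201), while injury (2.34e-06) and macrophage genes (0.0181) stayed. The injury score of HET minus WT was 0.329 under PBS, and −0.0308 under cisplatin without HET cisplatin 6. Without that library most of the injury difference thus lay between the PBS groups. Without the 3 libraries that stand apart the matrix (0.186) and endothelial calls (0.0857) were lost, and without the 5 libraries that go against their label the clock call was lost (0.0541). With an estimated correlation 0 lists were called in each of these 3 fits (smallest adjusted p 0.283, 0.207 and 0.327).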

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

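The values in this part were found by 2 rules fixed beforehand, a library that lies far from the others of its group and a list whose cisplatin response differs by genotype, while every test of an explanation for the first 2 patterns was chosen after the result was seen. In 548 groups of values looked at, 75 values lay far from the rest by Dixon's test, and chance alone gives about 1 in 20.

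The first pattern is Nbl1 and Htr6 against the genotype label in 5 libraries. The library labelled WT PBS 6 held 3.71 CPM of Nbl1 and 0.756 CPM of Htr6, far from the other WT PBS libraries. The 4 low libraries labelled HET were not shallow, since the smallest total was 31, in units of 1e6 counts, against 26.87 for the smallest other HET library. Another genotype than the label, with 2 targeted copies, might hold for HET cisplatin 3 and 4, where the lower Htr6 value was 3.58 CPM against at most 1.93 CPM in the rest. For HET PBS 1 and 6 Htr6 alone left this undecided, at 0.78 CPM against at most 0.826 CPM. Their Nbl1, at 1.67% and 6.82% of the WT mean, was near that of HET cisplatin 3 and 4 (5.22% and 4.17%). Nbl1 picked these 4 libraries out, so it is no separate evidence. For the library labelled WT PBS 6, its 3.71 CPM of Nbl1 lies within the level of 5 HET PBS libraries (up to 4.2 CPM), while a swap with a library labelled HET PBS fails, because the lowest HET PBS library holds 0.243 CPM of Htr6 against at most 0.0352 CPM in the other WT PBS libraries.

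The second pattern is a weaker response in WT cisplatin 6 and HET cisplatin 6. Mixture with RNA of a PBS kidney fails as an explanation, because the median share needed by the S1 and S2 genes was 27.7% (lower quartile 20.8%) and 27.9% (13.3%), while Kap allows 2.8% and 1.09%. Lower exposure to cisplatin in both animals could fit the erythrocyte score, of which the lower of the 2 was 2.02 against at most −0.53 in the other 14 cisplatin libraries, and the p53 target score, of which the higher of the 2 was 5.63 against at least 6.04 in the other 14. Both scores are themselves among the values flagged in these libraries. The first principal component goes the same way (at most 25.25 against at least 42.95) but also picked these libraries out, so none of these is separate evidence. Havcr1 was high in the one (438 CPM) and low in the other (31.6 CPM), so lower exposure stays undecided.

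In WT cisplatin 6 the low values were Nbl1 10.7, Eda2r 78.8, Sulf2 126, Phlda3 55.8, Zfp365 11.8 and Rev1 37.1 CPM and a p53 target score of 5.50. The high values there were Havcr1 438, Pvalb 0.696, Hbb-bs 12.8, Alas2 0.475, Cyp51 104 and Hmgcs1 433 CPM, with scores of 5.81 for cholesterol synthesis and 2.40 for erythrocyte genes. In HET cisplatin 6 the low values were Spp1 2350, Havcr1 31.6, Zmat3 233, Eda2r 66.4, Sulf2 125, Psrc1 19, Zfp365 10.2, Cxcl17 0.48, Casp14 1.28, Ano3 4.03, Celf5 2.05, Timp1 0.352, Col4a1 391, Itgam 1.22, Cd14 4.03, Cxcl2 0.352 and Kcnh1 0.544 CPM. Its scores were also low for injury markers (5.87), p53 targets (5.63), matrix (3.68), macrophage (1.63) and urothelium genes (0.563). Inmt 27, Casr 60, Hbb-bs 9.93 and Hba-a1 5.28 CPM and the erythrocyte score of 2.02 were high there.

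Other libraries held fewer such values. HET PBS 3 was high for Atp11a (2860 CPM), Cyp7b1 (278), Cyp51 (386), Rad51c (3.09) and the S3 score (9.05). HET cisplatin 8 was low for Slc4a4 (455 CPM), Slc12a3 (134), the distal convoluted tubule score (4.41) and the intercalated cell score (3.09). The library labelled WT PBS 6 was high for Pvalb (12.6 CPM). WT PBS 4 was low for Zmat3 (44.9 CPM) and high for Slc7a13 (1140 CPM) and the macrophage score (2.95). WT PBS 7 was high for Ypel2 (45.7 CPM) and low for Slc22a6 (775 CPM), and its Casp14 value (0.0377 CPM) is the 1 count of the whole WT PBS group, which stands apart by construction in whichever library holds it. WT cisplatin 4 was high for Col4a1 (816 CPM) and low for the adipose score (1.12). The library labelled HET cisplatin 4 was high for Akr1b7 (42.1 CPM) and Star (205 CPM). Single values were C3 in HET cisplatin 2 (553 CPM, low), Eda2r in WT PBS 2 (0.2 CPM, low), Sprr2f in WT PBS 5 (0.106 CPM, high, where the group held 4 counts), Sprr2g in HET PBS 4 (0.521 CPM, high), Cyp4b1 in WT cisplatin 3 (425 CPM, high), the adipose score in WT PBS 1 (−1.08, low) and the score of BMP ligands, receptors and antagonists in HET cisplatin 5 (3.18, low). Smad6 in WT PBS 8 (4.61 CPM), Tie1 in WT cisplatin 3 (25.5 CPM) and in HET PBS 4 (27.7 CPM) and Dbp in WT PBS 7 (28.8 CPM) also lay far from their groups.

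For 10 lists camera, which ranks a list against the other genes, called the interaction, while 0 genes passed singly. Injury markers (adjusted p = 6.09e-10), macrophage genes (0.000253), BMP targets (0.000534), BMP ligands, receptors and antagonists (0.0148), clock genes (0.0178) and matrix genes (0.0193) ranked on the lower side in HET, and interferon response (7.31e-05), S1 and S2 (0.000787), cholesterol synthesis (0.000787) and endothelial genes (0.0344) lay the other way. No call held with an estimated correlation or with fry, so a differing response is not shown, and 0 lists were called with an estimated correlation in the fits with libraries left out. Without HET cisplatin 6 the matrix (0.692) and endothelial calls (0.0843) were lost while injury (2.34e-06) and macrophage genes (0.0181) stayed, and without the 5 libraries that go against their label the clock call was lost (0.0541). Without HET cisplatin 6 the injury score differed by genotype mostly under PBS (HET minus WT 0.329, against −0.0308 under cisplatin).

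The libraries were also split into groups of the same sizes, and the counts of splits given here include the real one. For cisplatin the real groups gave 11761 genes in WT and 10544 in HET, reached by 1 of 100 splits each, the real one alone, with 8209 and 6276 as the highest of the others, from splits that kept 14 of 16 and 13 of 15 libraries on their own side. For genotype under cisplatin the real groups gave 1 gene, reached by 2 of 100 splits, the real one and 1 other (highest other 1), and averaged they gave 1, reached by 2 of 60, again the real one and 1 other. Under PBS the genotype gave 0 genes (highest other 2) and the interaction 0, so that all 100 of 100 and 60 of 60 splits reach these counts by construction and say nothing about chance. The highest other splits for the averaged genotype and the interaction, with 1087 and 1445 genes, sorted the cisplatin libraries by degree of response (first principal component 15.85 to 59.06 against 48.86 to 78.87), which points to a structure among the samples.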

How the results depend on the processing

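Leaving out the 5 libraries that go against their label, leaving out 3 libraries that stand apart, leaving out HET cisplatin 6 in the list tests, an estimated correlation in the list tests with libraries left out, library totals, thinned counts and clock phase were alternatives chosen after the result was seen, and the rest were chosen before the data were examined. Among the main results, 345 comparisons with earlier alternatives and 44 with later ones kept their direction and call, and 28 and 16 moved. Among named genes, lists and scores, 4276 and 1690 kept direction and call, 197 and 174 grew weaker, 13 and 2 grew stronger, and 19 and 9 reversed. The cause was not tested unless stated.

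The count of genes changed by cisplatin was 12174 in WT and 11374 in HET, and 11747 to 12347 and 10912 to 11728 when 1 library was left out. It was 9943 and 9858 in the shared range of animal numbers alone and 11824 and 10137 without the 5 libraries, both with fewer samples, and 12519 and 11560 without 3 libraries that stand apart. Library totals gave 14693 and 14392.

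Genotype under PBS gave 0 genes in edgeR, 5 with DESeq2, 2 without the 5 libraries and 0 to 2 with 1 library left out. Genotype under cisplatin gave 1, and 2 with limma voom or without the 5 libraries. Averaged, it gave 1, and 2 with DESeq2, limma voom, limma on TPM or without the 5 libraries. With 1 library left out it gave 1 to 2 averaged. The 5 libraries were picked by Nbl1 and Htr6, so calls of these genes gained without them are no separate evidence. For the other changes the cause was not tested. The log2 fold change of Nbl1 ran from −1.36 to −1.01 under PBS and from −1.69 to −1.32 under cisplatin with 1 library left out, and the interaction stayed at 0 genes.

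List calls depended on the allowance for correlation between genes. With an estimated correlation they went from 14 to 3 for cisplatin in WT, from 12 to 2 in HET, from 1 to 0 for genotype under PBS, from 11 to 0 under cisplatin, from 10 to 0 averaged and from 10 to 0 for the interaction. Fry called 25, 30, 0, 0, 0 and 0. For genotype under PBS there were 6 calls in the shared range of animal numbers, 6 with 2 surrogate variables and 7 without the 5 libraries, and averaged 5 with 2 surrogate variables. The cause was not tested. In the shared range of animal numbers the averaged direction turned for endoplasmic reticulum stress genes (adjusted p = 0.53) and p53 targets (adjusted p = 0.957). For genotype under cisplatin the matrix list turned without HET cisplatin 6 (adjusted p = 0.617, and 0.908 with an estimated correlation). Without the 5 libraries, without the 3 that stand apart and without HET cisplatin 6, an estimated correlation left 0 calls for genotype under PBS, genotype under cisplatin, averaged and the interaction. The correlation of the WT and HET fold changes was 0.979 at a mean CPM of at least 5 and 0.915 in the shared range of animal numbers, where fewer genes and fewer samples enter.

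With 1 library left out, the HET minus WT difference under cisplatin ran from −0.09 to 0.0792 for the p53 target score (reversed at −0.09, −0.0264, −0.0205, −0.0105, −0.00883, −0.00771 and −0.00141) and from −0.195 to 0.0257 for the cell cycle score. The injury score ran from −0.238 to −0.0308. Star under cisplatin turned to −0.155 with DESeq2, −0.161 without the 5 libraries, −0.173 without 3 libraries, and with 1 library left out it ran from −0.153, without the library labelled HET cisplatin 4 that holds the Star reads, to 4.08. Akr1b7 for cisplatin in HET turned to −0.825, −0.829 and −0.823 with the first 3 of these. With limma on TPM, Mcm6 (0.0185) and Nr1d2 (0.0095) in WT and Smad6 (0.12), Pdia4 (0.0251), Tie1 (0.0549) and Magi2 (0.108) in HET reversed. Nr1d2 also did with the clock covariate (0.0486) and Smad6 with library totals (0.0935). Htr6 for cisplatin in WT was 0.239 without the 5 libraries, since its PBS counts came from the library labelled WT PBS 6. For the other genes the cause was not tested. Genes of few counts have wide counting intervals, as Htr6 under cisplatin, with 3 counts in WT and a ratio interval of 59.6 to 852. With counts thinned to the smallest total, 321 of 323 fold changes of named genes kept direction and call and 2 grew weaker. In the simulation, within the limits given for it, 2-fold changes in the interaction were recovered in 61.2% of genes.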

Other observations

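In this part the clock covariate, its test on Ypel2 and the scaling by library totals were chosen after the data were seen, while the test on the other 4 genes was written before their values with the covariate were seen, though how Sesn2 follows Arntl had been looked at. Among genes of BMP signalling, Grem1, gremlin 1, rose by a log2 fold change of 4.68 (SE 0.57, n = 8 each) in WT and 3.71 (SE 0.55, n = 7 and 8) in HET, and Fst, follistatin, by 2.30 (SE 0.26) and 1.62 (SE 0.27). The ligand gene Bmp6 rose by 0.87 (SE 0.094) and 0.62 (SE 0.098). Of 16 genes of BMP ligands, receptors and antagonists 7 rose and 2 fell in WT and 6 rose and 1 fell in HET (the same adjusted over the list alone; camera 0.155 and 0.345), and with library totals 11 rose and 0 fell and 12 rose and 1 fell. Of 11 BMP targets 1 rose and 1 fell in WT and 4 fell in HET (1 and 1, and 3, adjusted over the list alone; camera 0.927 and 0.426), and with library totals 7 rose and 0 fell in WT and 2 rose and 1 fell in HET, where the median turned from −0.17 to 0.24. Smad7 fell by 0.54 (SE 0.13) and by 0.71 (SE 0.13).

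Further lists were not called by camera for cisplatin in either genotype; counts adjusted over the list alone equal these unless given. Of 9 intercalated cell genes 5 fell and 1 rose in each (4 and 3 in WT and 3 and 3 in HET with library totals). Of 11 podocyte genes 4 rose and 3 fell in WT and 5 and 3 in HET (HET median −0.01, mean 0.02; with library totals 7 and 2, and 8 and 1), and of 10 fibroblast and mural cell genes 4 and 5 rose and 1 fell (8 rose and 1 fell in each with library totals), with Notch3 up by 1.52 (SE 0.13) and 1.58 (SE 0.14) and Ren1, renin, down by 1.24 (SE 0.12) and by 1.18 (SE 0.12). Of 13 interferon response genes 3 rose and 4 fell in WT (median 0.10, mean −0.20) and 5 and 2 in HET (6 and 3, and 8 and 1, with library totals). Of 6 T and NK cell genes 3 and 4 fell (5 in HET adjusted over the list alone; 3 and 1 with library totals), of 7 B and plasma cell genes 5 and 3 fell (4 fell and 1 rose in WT with library totals), and of 6 neutrophil genes 1 and 5 fell (0 in WT adjusted over the list alone; with library totals 1 rose in WT and 1 fell in HET). Of 13 endoplasmic reticulum stress genes 7 fell and 3 rose in WT, where the median turned from −0.37 to 0.03 with library totals, and 6 and 2 in HET (6 and 3 adjusted over the list alone); with library totals 4 fell and 4 rose in WT and 1 fell and 3 rose in HET. Of 14 clock genes 5 fell and 3 rose in WT and 6 fell in HET, with medians that turned from −0.25 to 0.15 and from −0.34 to 0.06 with library totals (3 fell and 6 rose, and 4 fell and 5 rose). No immediate early gene of 10 passed (1 rose in each with library totals). Their score varied widely within the PBS groups, from 2.26 to 7.37 in WT PBS and from 2.37 to 7.86 in HET PBS. The lack of calls therefore does not show that these genes stayed level. Of 7 adipose genes 3 and 5 rose, and of 6 urothelium genes 4 and 5. The 1 pancreas gene fell in both and the 1 muscle gene passed in neither. Of the 16 genes around Nbl1 4 rose and 8 fell in WT and 5 and 6 in HET (7 and 2, and 8 and 2, with library totals), and of the 4 genes that check sex 1 rose and 2 fell in each (4 and 3 rose and 0 fell with library totals).

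The library labelled HET cisplatin 4 held 735 CPM in all over 7 adrenal gland genes, against at most 5.32 CPM in the libraries of the other groups. Star rose for cisplatin in HET by 4.23 (SE 0.97), from this library.

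The genes with the smallest p for genotype under PBS might reflect clock phase at collection. Arntl, a clock gene, stood at 11.8 CPM in WT PBS 7 and 11.9 to 22.9 CPM in HET PBS 4 to 7 (HET PBS 6 being one of the libraries that go against their label), and at 1.13 to 4.33 CPM in the other PBS libraries. In the cisplatin libraries it stood at 8.85 to 28.7 CPM, so clock phase and treatment are not cleanly separated either. With clock phase (Arntl minus Dbp) as a covariate, the log2 fold change of Ypel2 went from 0.84 (SE 0.18) to 0.40 (SE 0.14). The median size of the other 4 stayed at 0.716, from 0.793. Among these 4, Sesn2 (0.91 to 0.835), Rin2 (0.235 to 0.217) and Chrm3 (−0.676 to −0.597) shrank slightly, while Trim46 grew (−0.941 to −1.02). Clock phase could account for Ypel2 in part, while most of the size of the other 4 remained with the covariate. A smaller part of clock phase in these 4 is not excluded. The covariate rests on Arntl and Dbp alone, and high Arntl under PBS lay mostly in HET libraries.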
